A study of Mus musculus with 11 samples.

How the data were processed

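Total RNA of 11 samples was hybridized to Affymetrix mouse expression arrays with 45101 probe sets. The samples were induced pluripotent stem cells from ventricular myocytes (ViPSC) and from tail tip fibroblasts (TiPSC) and genetically matched embryonic stem cells (ESC), with 3 arrays each, and the source cells, ventricular myocytes (VM) and tail tip fibroblasts (TTF), with 1 array each. The pluripotent cells grew on irradiated feeder fibroblasts, which were removed by differential plating before RNA was taken. The deposited values are log2 expression values made by RMA, which normalizes between arrays, per the authors' processing notes. These notes give no version, and the probe annotation file and software used for RMA are not stated in the sources available. No detection calls were available, and RMA compresses differences near background.

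The 64 control probe sets, the 932 probe sets with several gene symbols and the 9160 without a symbol were left out of the gene analysis. For each gene the probe set with the highest mean over the 11 arrays was taken from the 34945 probe sets with 1 symbol, which gave 18193 genes, of which 9010 had more than 1 probe set. Chromosomes and gene order came from a mouse RefSeq gene table matched by Entrez identifier, which held 34741 of these probe sets. No array was left out.

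Differences among ViPSC, TiPSC and ESC were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, a spread shared by the 9 arrays, and moderated two-sided tests from eBayes. Adjusted p values are Benjamini-Hochberg values over the 18193 genes, and a gene passed at an adjusted p under 0.05. Errors of log2 differences are standard errors from this fit, and errors of group levels are standard deviations of 3 arrays. The labels do not say that the replicates were separate cultures, so the p values measure the spread between these samples. The shared spread assumes that the 3 groups vary alike, but ViPSC arrays were the most alike and ESC arrays the least (mean correlations 0.998 and 0.988). The p values of TiPSC against ESC thus draw on ViPSC arrays outside that comparison. The p values of both comparisons against ESC can be too small. In 1 simulated data set per comparison, with each gene's mean and moderated spread, normal noise and no other differences, 66 or 67 genes were changed by each size. The fit recovered 37.3%, 41.8% and 31.3% of changes of 0.5 log2 units, 92.5%, 89.6% and 91.0% of changes of 1 and 97.0%, 100.0% and 100.0% of changes of 2, for ViPSC against TiPSC, ViPSC against ESC and TiPSC against ESC. False calls made up 5.03%, 6.67% and 3.27% of the calls. The simulated genes were independent and the simulated groups varied alike, unlike the real groups. These rates therefore do not give the error rates of the real comparisons.

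Before the data were examined, 32 gene lists were fixed, with 727 entries, of which 668 were measured. They covered pluripotency (core and naive, primed epiblast), germ layers and other lineages (primitive streak and mesoderm, endoderm, trophoblast, neural cells, 2-cell-like genes, germline), heart muscle (transcription factors, sarcomere, calcium handling with channels and hormones), other cell types the samples could hold (fibroblasts and feeders, smooth muscle, endothelium, blood, keratinocytes, skeletal muscle), imprinting and sex chromosomes (Dlk1-Dio3 cluster, other imprinted genes, Y-linked genes, X inactivation, X-linked dosage), Hox genes, chromatin (DNA methylation and polycomb), and cell state (cell cycle, p53 and senescence, glycolysis and hypoxia, mitochondria, interferon and MHC class I, cholesterol and lipids, stress, and Wnt, LIF and TGF-beta targets). Each list was tested with camera at its preset correlation of 0.01, adjusted over the 32 lists of a comparison, and beside it with an estimated correlation and with fry, which asks whether the genes of a list move in 1 direction without comparing them with other genes. Members were counted after adjustment over all genes and over the list alone.

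VM and TTF were compared with each other and with the induced cells without a test, by counting genes that differed by at least 2 log2 units, for induced cells in all 3 arrays. List medians between VM and TTF were ranked among 10000 random lists of genes with like mean levels. VM-high genes were at least 2 log2 units higher in VM than in TTF and than in the ESC mean, and TTF-high genes the same for TTF. The residual share of such a gene was its induced minus ESC log2 difference as a percentage of its source minus ESC log2 difference. It is given as the median over genes from group means and is not a share of transcripts. For chromosomes, genes with a mean of at least 7 over the pluripotent arrays were called expressed, and each array was set against the mean of the 9 arrays after centring on the median of the expressed autosomal genes.

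The genes named were fixed by a rule before the data were examined. For each replicated comparison these were the 10 largest differences in each direction among genes past the threshold without overlap of the arrays, and up to 4 members of each list past the threshold, or the 1 or 2 with the largest difference where none passed. For the comparisons with source cells they were the 10 largest differences in each direction and up to 4 members of each list, and Pou5f1, Nanog and Sox2 were named in every group. Clone and locus names were counted but not named, and some list members and genes of the source comparisons were left out of the text for length. Of 66 named gene and comparison pairs with several probe sets, 25 had another probe set past the threshold in the same direction and 0 had a probe set past it in the opposite direction in limma. Probe sets of some named genes went both ways. Among these were Sgce (1 of 2 in the direction given) and Ccn1 (2 of 4) between ViPSC and TiPSC, and Eif2s3y (1 of 2) between ViPSC and ESC. For others, such as Ldb3 between ViPSC and TiPSC, 0 probe sets passed when every probe set was tested.

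The alternatives fixed beforehand were quantile normalization again, median centring, leaving out the genes below the median mean level, the mean of all probe sets of a gene, every probe set, eBayes with trend and robust settings, a fit of the 6 compared arrays or of all 11, the replicate number as a block, a difference of at least 1 log2 unit, the other list tests, other sizes and definitions for the source comparisons, and leaving out each array in turn. In the fits without an array, the group of 2 shared the spread of the other groups. A fit without the genes of chromosomes 8, 11, X and Y was added after the data were seen.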

Results

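Affymetrix mouse expression arrays measured total RNA from 5 kinds of mouse cells of a mixed C57/Bl and BlackSwiss background. The replicated groups were induced pluripotent stem cells made from ventricular myocytes (ViPSC, n = 3 arrays), induced pluripotent stem cells made from tail tip fibroblasts (TiPSC, n = 3) and genetically matched embryonic stem cells (ESC, n = 3). The source cells, ventricular myocytes (VM) and tail tip fibroblasts (TTF) from pups at postnatal day 1, had 1 array each and therefore no replicates. The values were log2 RMA expression values for 45101 probe sets, reduced to 18193 genes. The number of arrays limits the precision of every comparison, and the labels do not say whether the 3 arrays of a group came from separate cultures.

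The pluripotency regulators Pou5f1, Nanog and Sox2 were at similar levels in the 3 groups of pluripotent cells and near the bottom of the scale in the source cells. Mean log2 Pou5f1 was 12.74 ± 0.01 in ViPSC, 12.90 ± 0.07 in TiPSC and 13.01 ± 0.05 in ESC (SD, n = 3), against 3.73 in VM and 3.94 in TTF. Nanog was 12.68 ± 0.07, 12.47 ± 0.10 and 12.78 ± 0.42 in the same order, and 3.53 in VM and 3.95 in TTF. Sox2 was 12.04 ± 0.09, 12.05 ± 0.12 and 12.27 ± 0.17, and 2.81 in VM and 4.23 in TTF. Across genes, which are not independent replicates, the mean Pearson correlation between arrays was 0.998 within ViPSC, 0.995 within TiPSC and 0.988 within ESC. Between groups it was 0.991 for ViPSC with TiPSC, 0.990 for ViPSC with ESC and 0.988 for TiPSC with ESC. On average, ESC arrays thus differed from each other about as much as from the induced cells. ESC 1 was nearer to the induced cells, with correlations of 0.993 to 0.994, than to ESC 2 (0.988) and ESC 3 (0.984). ESC 2 and ESC 3 correlated at 0.993, so the ESC mean joins unlike arrays. ViPSC and VM correlated at 0.831, TiPSC and TTF at 0.854, and VM and TTF at 0.874. ViPSC and TTF correlated at 0.846, TiPSC and VM at 0.834, and ESC at 0.847 with TTF and 0.829 with VM. All 3 pluripotent groups thus lay nearer to the TTF array than to the VM array, whatever their origin.

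**Figure D1:**
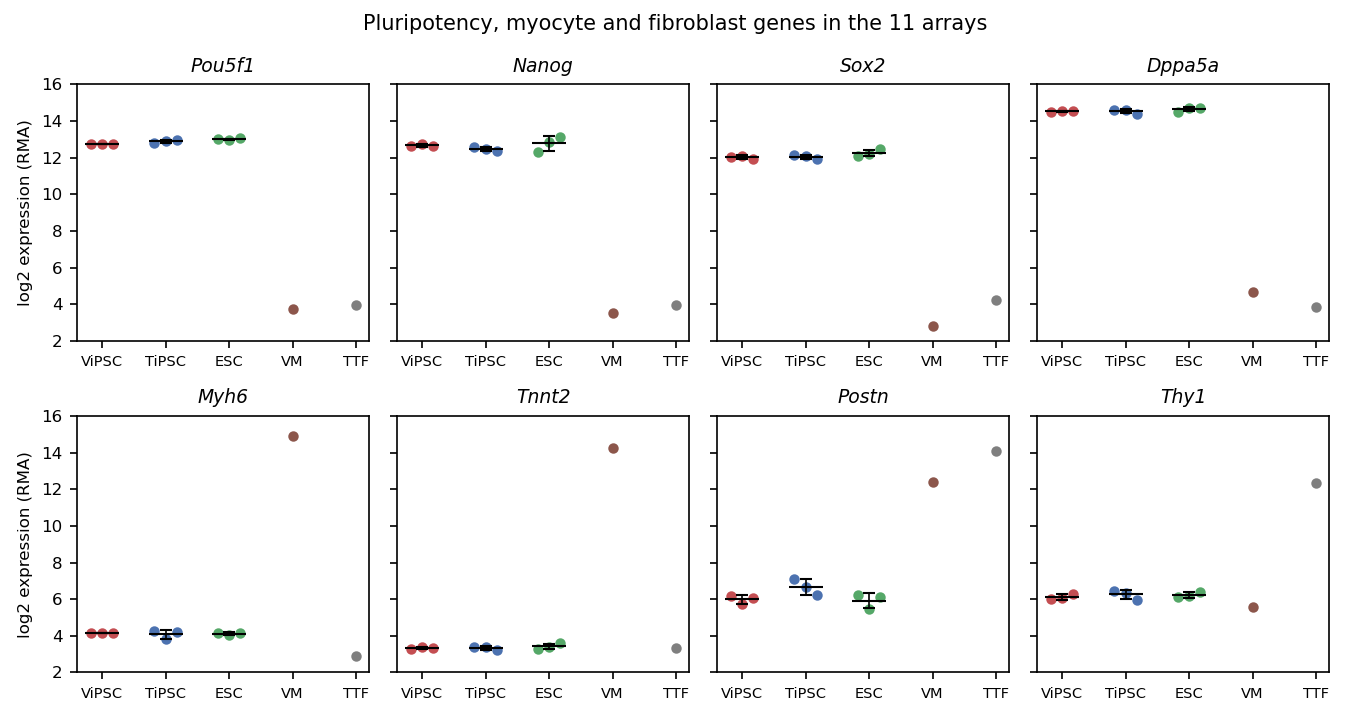
Log2 expression (RMA, vertical axis) of 4 pluripotency genes, the myocyte genes Myh6 and Tnnt2 and the fibroblast genes Postn and Thy1 in each cell group, where points are arrays and bars are the mean ± SD of 3 arrays. Pou5f1 lies between 12.74 and 13.01 in the pluripotent group means, and Myh6 reaches 14.90 in the VM array alone.

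VM against TTF asks how far the starting cells differed. The VM array carried the contractile program of the heart. Myh6, the alpha cardiac myosin heavy chain, was at 14.90 in VM and 2.89 in TTF. Myl2, the ventricular myosin regulatory light chain, was at 15.02 and 3.96, and Tnnt2, cardiac troponin T, at 14.28 and 3.34. Of 28 cardiac sarcomere genes 26 were at least 2 log2 units higher in VM (list median difference 8.06). So were 12 of 22 cardiac transcription factors (2.59), 19 of 25 calcium-handling, channel and hormone genes (4.33) and 20 of 33 genes of mitochondrial respiration and fatty acid oxidation (2.24). Fibroblast genes were high in the TTF array: Thy1, a fibroblast surface antigen, was at 12.36 against 5.55 in VM, S100a4 at 13.85 against 6.17. Dkk2, a Wnt antagonist, was at 12.08 against 3.94, and Crabp1, a retinoic acid binding protein, at 13.78 against 4.51. Of 38 fibroblast and feeder markers 24 were at least 2 log2 units lower in VM (list median −2.86). Genes of other cell types were measured in the VM array as well. All 16 endothelial genes were at least 2 log2 units higher in VM than in TTF (list median 5.35), with the adhesion gene Cdh5 at 11.61 against 3.72. The fibroblast list had a median level of 9.88 in VM against 13.08 in TTF. In all, 1693 of 18193 genes differed by at least 2 log2 units, 852 higher and 841 lower in VM, without a test.

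Each kind of induced cell against its source cell asks what changed with reprogramming. Dppa5a, a marker of naive pluripotency, was at 14.54 ± 0.02 in ViPSC against 4.66 in VM, and at 14.55 ± 0.12 in TiPSC against 3.87 in TTF (SD, n = 3). L1td1, an RNA-binding protein of pluripotent cells, was at 12.93 ± 0.01 and 12.86 ± 0.17 in ViPSC and TiPSC, against 4.62 in VM and 3.83 in TTF. Tdgf1, the Nodal co-receptor Cripto, was at 12.71 ± 0.06 and 12.90 ± 0.08, against 4.46 and 4.18. Cardiac sarcomere genes had a median level of 4.87 in ViPSC and 12.98 in VM. Among cardiac genes in ViPSC, Myh6 was at 4.15 ± 0.01, Tnnt2 at 3.32 ± 0.04 and Pln, the inhibitor of the sarcoplasmic calcium pump, at 3.64 ± 0.07 against 13.36 in VM. The fibroblast and feeder list had a median level of 7.77 in TiPSC, 7.21 in ESC and 13.08 in TTF. Within TiPSC, Postn was at 6.65 ± 0.45 against 14.08 in TTF, Dcn at 5.48 ± 0.19 against 13.26 and Thbs4 at 4.05 ± 0.07 against 13.20. Xist, the RNA that silences the X chromosome, was at 11.50 in VM and 11.06 in TTF and at 6.15 ± 0.11 in ViPSC and 6.09 ± 0.22 in TiPSC. Both source arrays also held the Y-linked Eif2s3y, at 8.28 in VM and 8.39 in TTF, so for Xist the sex of the cells is not separated from reprogramming. Counting genes that differed by at least 2 log2 units in all 3 arrays, ViPSC differed from VM in 2402 genes (1172 higher, 1230 lower) and TiPSC from TTF in 1913 (820 higher, 1093 lower), and 552 genes were higher in both.

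ViPSC against TiPSC asks how the induced cells of the 2 origins differed. Each group may hold 1 line. The cell of origin is therefore not separated from other differences between the lines, such as the chromosome shifts given below. Among the genes the rule names, the largest rise was that of Pnma5 on chromosome X (3.46 ± 0.81, adjusted p = 0.0417; SE, n = 3 per group), and the largest fall that of Csrnp3 (−1.97 ± 0.28, adjusted p = 0.00745). Rhox9, a reproductive homeobox gene on chromosome X, was 3.43 ± 0.39 log2 units higher in ViPSC (10.63 against 7.20, with adjusted p = 0.00252). Rhox6, its neighbour in the same family, was 3.13 ± 0.34 (adjusted p = 0.00222) higher and Khdc3, part of a maternal protein complex of the oocyte, 2.99 ± 0.30 (adjusted p = 0.00176). Rbm44, an RNA-binding protein of germ cells, was higher by 2.87 ± 0.16 (7.60 against 4.73, with adjusted p = 0.000263) and Plac1, a placental gene on chromosome X, 2.56 ± 0.35 (adjusted p = 0.00586). Igf2, the imprinted growth factor, was 2.06 ± 0.28 higher in ViPSC (adjusted p = 0.00573), and Mep1b, a subunit of the metalloprotease meprin, 2.71 ± 0.18 (adjusted p = 0.000379). Also among the 10 highest were Fmr1nb (2.66 ± 0.62, adjusted p = 0.0411) and Nrk (2.58 ± 0.34, adjusted p = 0.00566) on chromosome X and Mt4 on chromosome 8 (2.63 ± 0.18, adjusted p = 0.000454). Lower in ViPSC were Chac1, a glutathione-degrading enzyme of the stress response (−1.84 ± 0.28, adjusted p = 0.00962), Herpud1, a gene of endoplasmic reticulum stress on chromosome 8 (−1.75 ± 0.25, adjusted p = 0.00769). Gli2, a transcription factor of Hedgehog signalling, was lower (−1.62 ± 0.32, adjusted p = 0.0240), as were the imprinted genes Mest (−1.42 ± 0.15, adjusted p = 0.00208) and Sgce (−0.997 ± 0.18, adjusted p = 0.0179). The 10 lowest also held Cdk6 (−1.56 ± 0.21, adjusted p = 0.00597), Tmem47 on chromosome X (−1.535 ± 0.24, adjusted p = 0.00926), Hunk (−1.385 ± 0.15, adjusted p = 0.00226) and Mthfd2l (−1.35 ± 0.17, adjusted p = 0.00424). Of 34 genes of DNA methylation and polycomb machinery 4 were higher and 0 lower in ViPSC, and the list did not pass (median −0.03, mean 0.12, adjusted p = 0.365). These were the polycomb repressive complex components Phf19 (1.78 ± 0.22, adjusted p = 0.00424), Suz12 (0.95 ± 0.12, adjusted p = 0.00424; chromosome 11) and Jarid2 (0.57 ± 0.09, adjusted p = 0.0110) and the DNA methyltransferase Dnmt3a (0.91 ± 0.20, adjusted p = 0.0350), and for Phf19 1 of its 2 probe sets was higher.

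In the limma fit 1024 of 18193 genes passed the threshold between ViPSC and TiPSC, 582 higher and 442 lower in ViPSC, and 173 of them differed at least 2-fold (140 higher, 33 lower). For all 1024 the arrays of the 2 groups did not overlap, as for 6098 of all genes, where random grouping gives 10%. The count fell to 241, 207 and 207 without ViPSC 1, ViPSC 2 and ViPSC 3, to 255 without TiPSC 1 and to 512 without TiPSC 2. With any 1 array left out, 33 to 55 of the 65 named genes past the threshold still passed. The count rose to 2621 (1380 higher) in a fit of the 6 compared arrays alone, which kept all 65, and was 1635 (974 higher) with every probe set tested. Without the genes of chromosomes 8, 11, X and Y it was 607 (280 higher), an alternative added after the data were seen.

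**Figure D2:**
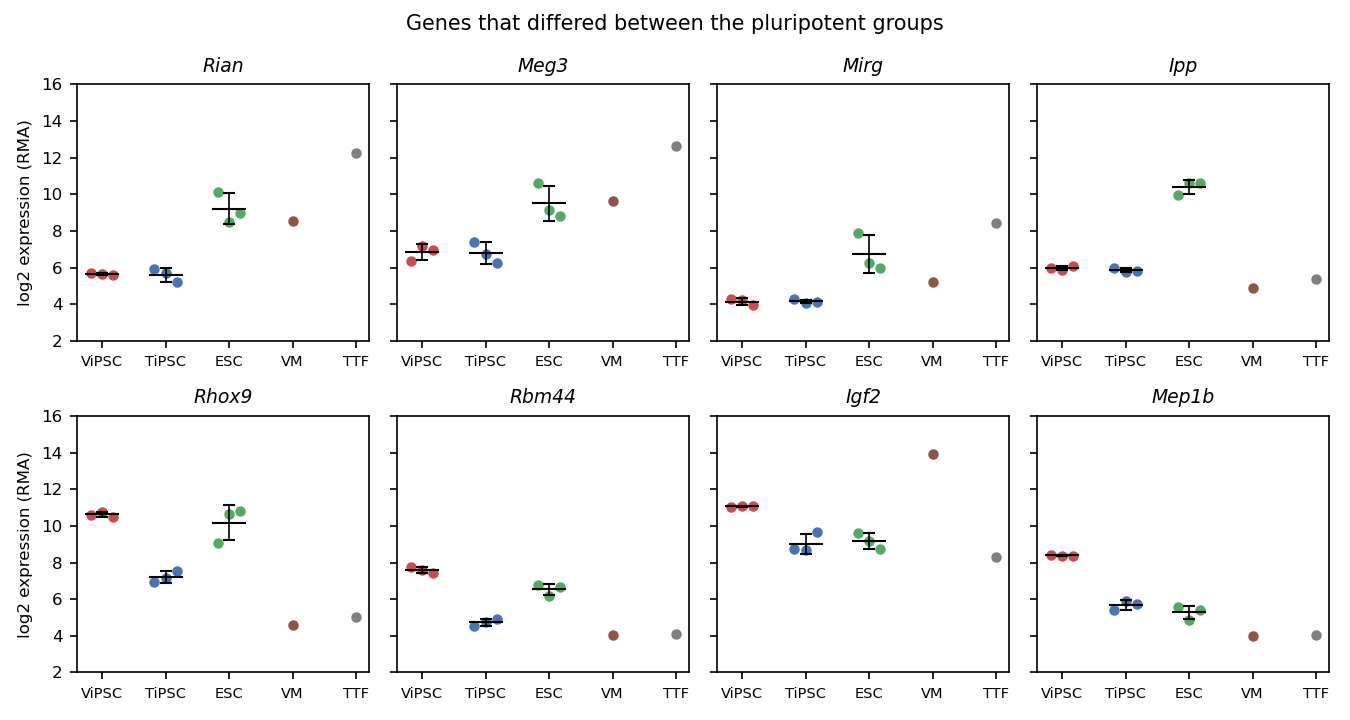
Log2 expression (RMA, vertical axis) of 8 genes that differed between the pluripotent groups, where points are arrays and bars are the mean ± SD of 3 arrays. Rhox9 is at 10.63 in ViPSC and 7.20 in TiPSC, and Rian is at 5.64 in ViPSC, 5.62 in TiPSC and 9.21 in ESC.

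Of the 32 gene lists, 7 were called between ViPSC and TiPSC by camera, and none with an estimated correlation (lowest adjusted p = 0.278). Trophoblast genes were higher in ViPSC as a group (list median 0.47, adjusted p = 6.24e-07): 4 of 14 rose over all genes, and 6 when adjusted over the list alone. For trophoblast genes adjusted p = 0.278 with an estimated correlation, in a range of 2.20e-08 to 0.278 over the alternatives. Next to Plac1 these were Krt7, a simple-epithelial keratin (2.05 ± 0.39), Gata3, a trophoblast transcription factor (1.63 ± 0.18), and the imprinted regulator Ascl2 (1.01 ± 0.11). Germline genes were higher (median 0.09, adjusted p = 0.00575), with 6 of 25 past the threshold over all genes and 6 adjusted over the list alone, among them Rhox9, Rhox6, Tex19.1 (1.46 ± 0.23; chromosome 11) and Taf7l (1.23 ± 0.28; chromosome X). For germline genes adjusted p = 0.684 with an estimated correlation, in a range of 0.00380 to 0.684 over the alternatives. Without the genes of chromosomes 8, 11, X and Y the germline list was no longer called (adjusted p = 0.164).

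Interferon and MHC class I genes were higher in ViPSC (median 0.18, adjusted p = 0.0242). For interferon and MHC class I genes adjusted p = 0.670 with an estimated correlation, in a range of 0.0109 to 0.670 over the alternatives. The 2 of 24 that rose were Irf1 (1.48 ± 0.13) and Ifi35 (2.49 ± 0.47), both on chromosome 11, and 4 were higher and 2 lower when adjusted over the list alone. This call ended without TiPSC 3 (adjusted p = 0.0816) and without the genes of chromosomes 8, 11, X and Y (adjusted p = 0.132). Endothelial genes were higher (median 0.06, adjusted p = 0.0273), with 2 of 16 past the threshold, Pecam1, an adhesion molecule on chromosome 11 (1.33 ± 0.21), and the tight junction gene Cldn5 (1.03 ± 0.13), and with 4 higher and 1 lower adjusted over the list alone. For endothelial genes adjusted p = 0.410 with an estimated correlation, in a range of 0.0167 to 0.410 over the alternatives. The endothelial call ended without ViPSC 2 (adjusted p = 0.0688) or TiPSC 1 (adjusted p = 0.0707), with the mean of all probe sets (adjusted p = 0.0524) and without the genes below the median mean level (adjusted p = 0.227). Leaving out the latter genes also ended the germline and stress calls (adjusted p = 0.0670 for both), and of the 7 calls fry kept those of trophoblast, endothelial and cholesterol genes.

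Cholesterol and lipid synthesis genes were lower in ViPSC (median −0.39, adjusted p = 0.00532). For cholesterol and lipid synthesis genes adjusted p = 0.684 with an estimated correlation, in a range of 1.63e-05 to 0.684 over the alternatives. The enzymes Msmo1 (−1.27 ± 0.16; chromosome 8), Cyp51 (−0.86 ± 0.11) and Idi1 (−0.68 ± 0.12) fell, 3 of 19, and 12 were lower and 2 higher when adjusted over the list alone. Stress and immediate early genes were lower (median −0.44, adjusted p = 0.0242), with Chac1 and the heat shock gene Hspa1a (−0.90 ± 0.18) lower and Ier3 higher (0.50 ± 0.10) of 23, and 6 lower and 1 higher adjusted over the list alone. For stress and immediate early genes adjusted p = 0.786 with an estimated correlation, in a range of 0.00627 to 0.786 over the alternatives. The stress call ended without TiPSC 3 (adjusted p = 0.0502) and without the genes of chromosomes 8, 11, X and Y (adjusted p = 0.120). Fibroblast and feeder markers were lower in ViPSC as a group (median −0.34, adjusted p = 0.00528), although of the 3 of 38 past the threshold the matrix protein gene Sparc (1.06 ± 0.08) and the growth factor binding protein gene Igfbp4 (1.07 ± 0.15), both on chromosome 11, were higher and the matricellular gene Ccn1 (−0.50 ± 0.09) was lower. For fibroblast and feeder markers adjusted p = 0.839 with an estimated correlation, in a range of 3.11e-05 to 0.839 over the alternatives. Adjusted over the list alone, 6 were lower and 2 higher, and the call ended without TiPSC 1 (adjusted p = 0.158), the array with the highest level of this list (median 0.57 above the mean of the 9 pluripotent arrays, against 0.21 in TiPSC 2 and 0.01 in TiPSC 3).

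**Figure D3:**
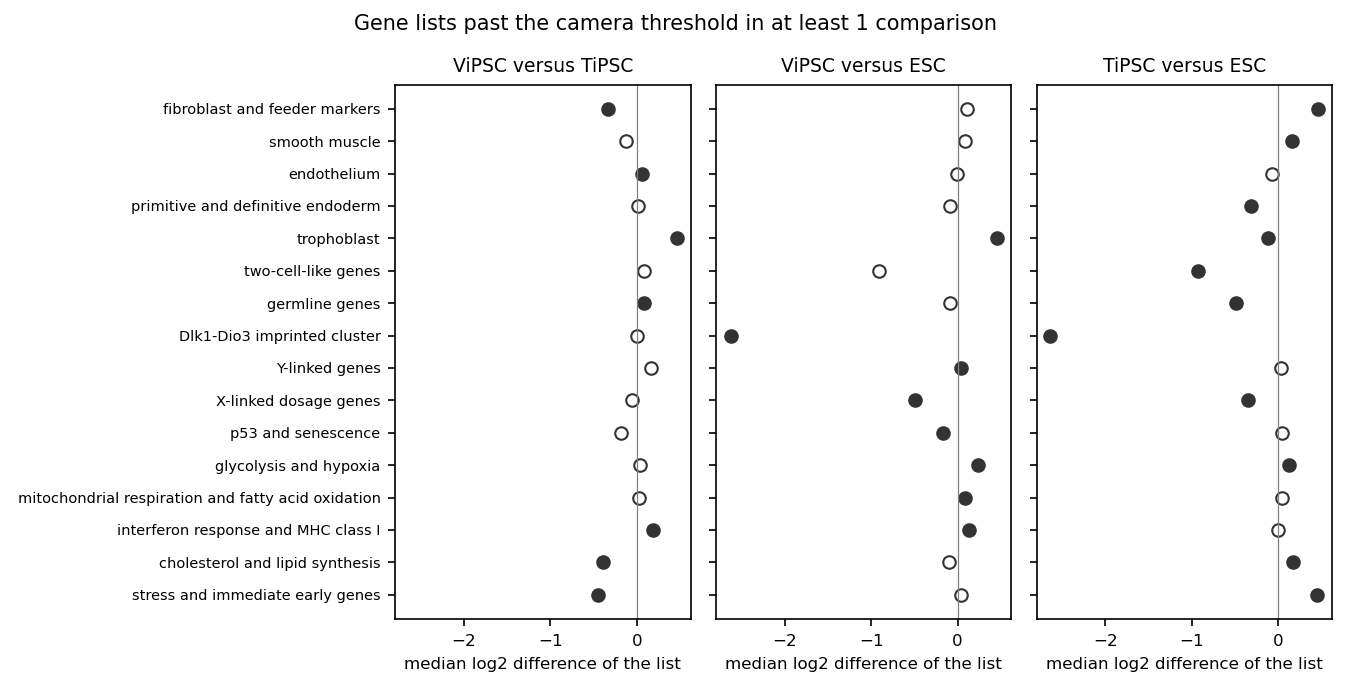
Median log2 difference (horizontal axis) of the 16 gene lists called in at least 1 of the 3 comparisons, 1 panel per comparison, where filled points passed camera with a preset correlation and none passed with an estimated correlation. The Dlk1-Dio3 cluster has medians of −2.62 and −2.64 against ESC, and the trophoblast list has a median of 0.47 between ViPSC and TiPSC.

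Whether each induced line held more transcripts of its own source cell was asked with 2 gene sets defined without the ViPSC and TiPSC arrays. The 596 VM-high genes, higher in VM than in TTF and in ESC, did not pass between ViPSC and TiPSC. Their median difference was −0.02, their mean 0.04, and camera gave an upward direction with adjusted p = 0.130. The set passed when it was defined by VM against TTF alone (median −0.0083, adjusted p = 0.0478) and when the genes below the median mean level were left out (median 0.0030, adjusted p = 0.0435), within a range over the alternatives of 0.0435 to 0.236. Within them 18 genes rose and 7 fell, and the contractile and calcium genes among these went both ways. Myl4, a myosin light chain on chromosome 11 (1.44 ± 0.22), and Hrc, a calcium-binding protein of the sarcoplasmic reticulum (0.96 ± 0.13), were higher in ViPSC, and Ldb3, a Z-disc gene (−0.67 ± 0.16), was lower. The 529 TTF-high genes were lower in ViPSC by a median of −0.11 (adjusted p = 0.0139), with 13 genes higher and 19 lower and 31.6% of the set above 0. Over all 18193 genes the median difference was −0.035. Part of the TTF-high shift was thus not particular to the set, and the VM-high median lay above that of all genes. For the 529 TTF-high genes adjusted p = 0.203 with an estimated correlation, in a range of 0.000958 to 0.203 over the alternatives. Among them Wls, needed for Wnt secretion (−1.39 ± 0.21), was lower, and 24 of the set belong to the fibroblast and feeder list. On the log2 scale from the ESC mean to the source cell, the median residual of TTF-high genes, from the group means, was 2.32% in TiPSC and −0.150% in ViPSC, and the mean of the 3 arrays was 2.53% (SD 0.982) and 0.0460% (SD 0.586). Without 1 array it was 2.00% to 2.85% in TiPSC and −0.531% to 0.0406% in ViPSC. That of VM-high genes was 0.0313% in ViPSC and 0.298% in TiPSC, with array means of 0.403% (SD 0.269) and 0.549% (SD 0.571). Without 1 array they were 0.208% to 0.352% in ViPSC and 0.236% to 0.703% in TiPSC, ranges that overlap. Their order turned when the genes below the median mean level were left out, to 2.84% in ViPSC and 1.35% in TiPSC, and without ViPSC 1, at 0.352% in ViPSC. The TTF-high call ended without TiPSC 1 (median −0.10, adjusted p = 0.119) and with a size of 1 log2 unit (median −0.0755, adjusted p = 0.141).

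Genes of whole chromosomes moved together in some arrays, which bears on a named gene only where the compared arrays differ for its chromosome. Between ViPSC and TiPSC the median difference of expressed genes was −0.06 on chromosome X (camera adjusted p = 0.901) and −0.23 on chromosome 8. The rises of genes named on chromosome X and of Mt4 on chromosome 8 in that comparison did not follow their chromosomes. Over 644 expressed genes of chromosome 11, the median ViPSC minus TiPSC difference was 0.44 and 94.4% were above 0 (camera adjusted p = 4.56e-23, with adjusted p = 0.647 with an estimated correlation). Of all 1443 chromosome 11 genes 247 rose and 6 fell. Against the mean of the 9 pluripotent arrays, chromosome 11 had medians of 0.26, 0.27 and 0.27 in ViPSC, −0.20 in each TiPSC array, −0.17 and −0.20 in ESC 1 and ESC 2, and 0.19 in ESC 3. Chromosome 8 had a median of 0.45 in TiPSC 3 alone, and chromosome X had medians of 0.65 in ESC 2 and 0.65 in ESC 3 against −0.15 in ESC 1. The medians of the other chromosomes lay between −0.08 and 0.10 in all 9 arrays.

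**Figure D4:**
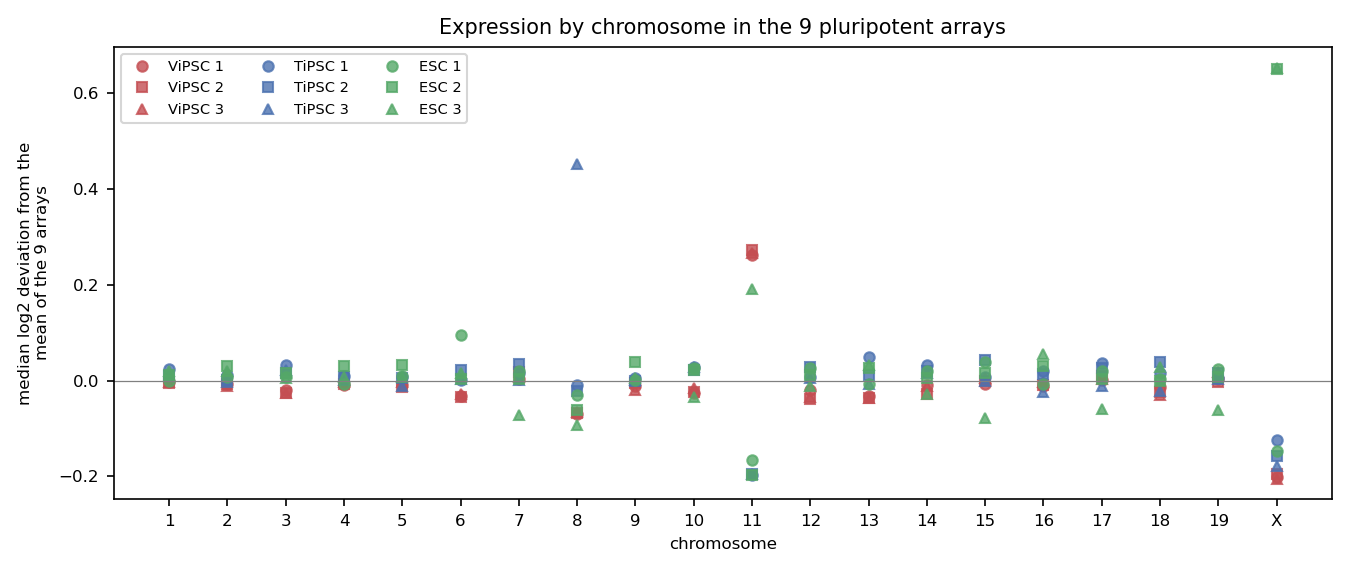
Median log2 deviation of expressed genes from the mean of the 9 pluripotent arrays (vertical axis) by chromosome (horizontal axis), where each point is 1 array. Chromosome 11 is at 0.26 to 0.27 in the 3 ViPSC arrays and at 0.19 in ESC 3, chromosome 8 at 0.45 in TiPSC 3, and chromosome X at 0.65 in ESC 2 and ESC 3.

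ViPSC against ESC asks how close the myocyte-derived line was to embryonic stem cells. The Y-linked Eif2s3y was at 3.73 to 4.22 in the ESC arrays and at 8.28 to 9.2 in the ViPSC arrays. Sex chromosomes and the line used are therefore not separated from induced against embryonic origin, here and for TiPSC against ESC. The maternally expressed noncoding RNAs of the Dlk1-Dio3 imprinted cluster were lower in ViPSC: Rian by −3.58 ± 0.36 (SE, n = 3 per group; 5.64 against 9.21, with adjusted p = 0.00431), Meg3 by −2.67 ± 0.46 (adjusted p = 0.0267) and Mirg by −2.58 ± 0.41 (adjusted p = 0.0212). Ipp, an actin-binding kelch protein gene, was at 5.98 against 10.41 (−4.43 ± 0.18, adjusted p = 1.27e-05). Higher in ViPSC were Eif2s3y, a Y-linked translation factor (4.81 ± 0.82, adjusted p = 0.0259), Mep1b (3.12 ± 0.18, adjusted p = 0.000215), Acp5, tartrate-resistant acid phosphatase (2.14 ± 0.14, adjusted p = 0.000509). Neurog1, a neural transcription factor, was higher too (2.10 ± 0.29, adjusted p = 0.0140), as was Igf2 (1.90 ± 0.28, adjusted p = 0.0162). The 10 highest also held Lrrc31 (2.35 ± 0.44, adjusted p = 0.0362), Mt4 (1.91 ± 0.18, adjusted p = 0.00376; chromosome 8), Cd2 (1.78 ± 0.23, adjusted p = 0.0121), Lrriq4 (1.72 ± 0.30, adjusted p = 0.0272) and Nrk (1.62 ± 0.34, adjusted p = 0.0498; chromosome X). Among the 10 lowest were Pcolce2 (−1.74 ± 0.35, adjusted p = 0.0442), Mb21d2 (−1.49 ± 0.17, adjusted p = 0.00663), Eda2r on chromosome X (−1.29 ± 0.22, adjusted p = 0.0260) and Mras (−1.265 ± 0.19, adjusted p = 0.0177). Amn (−1.20 ± 0.22, adjusted p = 0.0308) and Fgf15 (−1.185 ± 0.19, adjusted p = 0.0226) were lower too. Hrc (1.11 ± 0.13, adjusted p = 0.00910) and Mb, myoglobin (0.57 ± 0.12, adjusted p = 0.0478), the 2 of 25 calcium, channel and hormone genes past the threshold, were higher, at 6.27 and 5.56 against 10.51 and 15.00 in VM. For Mb 1 of its 2 probe sets was higher, and 0 passed when every probe set was tested. The list of calcium, channel and hormone genes as a whole did not pass between ViPSC and ESC (median −0.10, mean −0.01, downward test direction, adjusted p = 0.324).

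Between ViPSC and ESC 390 genes passed the threshold in the limma fit, 264 higher and 126 lower in ViPSC, and 78 differed at least 2-fold (56 higher, 22 lower). The count fell to 28, 23 and 22 without ViPSC 1, ViPSC 2 and ViPSC 3 and to 62 without ESC 2, and it was 2519 without ESC 1 and 607 without ESC 3. Of the 35 named genes past the threshold, 7 passed without any given ViPSC array, 12 without ESC 2, 29 without ESC 3 and 35 without ESC 1, and a fit of the 6 compared arrays alone left 73 genes and 14 of the 35. Without the genes of chromosomes 8, 11, X and Y the count was 184 (103 higher).

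Against ESC, 8 lists were called in ViPSC, and none with an estimated correlation (lowest adjusted p = 0.381). The Dlk1-Dio3 list was lower (adjusted p = 4.66e-05), with 3 of 4 members past the threshold over all genes and 3 adjusted over the list alone. For the Dlk1-Dio3 list adjusted p = 0.381 with an estimated correlation, in a range of 1.03e-05 to 0.381 over the alternatives. X-linked dosage genes were lower (median −0.49, adjusted p = 5.76e-10): 1 of 18 fell, Kdm5c, a histone demethylase gene (−0.64 ± 0.10), and 15 fell adjusted over the list alone, in a comparison where chromosome X was at 0.65 in ESC 2 and ESC 3 but at −0.15 in ESC 1. For X-linked dosage genes adjusted p = 0.436 with an estimated correlation, in a range of 5.74e-14 to 0.436 over the alternatives. Y-linked genes were higher (adjusted p = 0.0246), with Eif2s3y and Uba1y (1.52 ± 0.22) past the threshold of 7 and 3 adjusted over the list alone. For Y-linked genes adjusted p = 0.603 with an estimated correlation, in a range of 0.0103 to 0.603 over the alternatives. This call ended without ViPSC 2 (adjusted p = 0.0812) or ESC 1 (adjusted p = 0.196). Trophoblast genes were higher (median 0.46, adjusted p = 1.09e-04), with 1 of 14 past the threshold, Ascl2 (0.58 ± 0.11), and 6 adjusted over the list alone. For trophoblast genes adjusted p = 0.381 with an estimated correlation, in a range of 5.69e-06 to 0.381 over the alternatives.

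Of the 8 calls fry kept that of the Dlk1-Dio3 list. Genes of glycolysis and hypoxia were higher in ViPSC (median 0.24, adjusted p = 0.00944), with Aldoc, an aldolase gene on chromosome 11 (1.23 ± 0.24), the 1 of 23 past the threshold and 5 adjusted over the list alone. For genes of glycolysis and hypoxia adjusted p = 0.603 with an estimated correlation, in a range of 0.000636 to 0.603 over the alternatives. Interferon genes were higher (median 0.13, adjusted p = 0.0246), with the proteasome gene Psmb9 (1.11 ± 0.20) and Irf1 (0.77 ± 0.13) past the threshold of 24 and 5 adjusted over the list alone. For interferon genes adjusted p = 0.436 with an estimated correlation, in a range of 0.00627 to 0.436 over the alternatives. That call ended without ESC 1 (adjusted p = 0.114), without ESC 2 (adjusted p = 0.0976) and without the genes of chromosomes 8, 11, X and Y (adjusted p = 0.111). Mitochondrial genes were higher (median 0.08, adjusted p = 0.0246), with Acadvl, a fatty acid dehydrogenase gene on chromosome 11 (0.90 ± 0.15), the 1 of 33 past the threshold, and 2 higher and 1 lower adjusted over the list alone. For mitochondrial genes adjusted p = 0.568 with an estimated correlation, in a range of 0.0208 to 0.568 over the alternatives. It ended without ViPSC 1 (adjusted p = 0.0623), ESC 1 (adjusted p = 0.0836) or the genes of the 4 chromosomes (adjusted p = 0.0912). The p53 and senescence list was lower (median −0.17, adjusted p = 0.0246), with Cdkn2a, the cell cycle inhibitor gene (−0.72 ± 0.14), the 1 of 18 past the threshold and 3 adjusted over the list alone, and the call ended without ViPSC 1 (adjusted p = 0.0514), ESC 1 (adjusted p = 0.163) or ESC 2 (adjusted p = 0.0818). For the p53 and senescence list adjusted p = 0.436 with an estimated correlation, in a range of 0.00322 to 0.436 over the alternatives. Leaving out the genes below the median mean level ended the calls of trophoblast (adjusted p = 0.104), interferon (adjusted p = 0.104), glycolysis (adjusted p = 0.108), mitochondrial (adjusted p = 0.136) and p53 genes (adjusted p = 0.0716).

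TiPSC against ESC asks the same of the fibroblast-derived line. Rian (−3.59 ± 0.36, adjusted p = 0.00771; SE, n = 3 per group), Meg3 (−2.72 ± 0.46, adjusted p = 0.0439) and Mirg (−2.56 ± 0.41, adjusted p = 0.0341) were lower in TiPSC too, as was Ipp (−4.56 ± 0.18, adjusted p = 9.73e-06). Rhox9 and Rhox6 lie on chromosome X, which had a median of 0.65 in ESC 2 and ESC 3. In TiPSC Rhox9 was lower by −2.98 ± 0.39 (adjusted p = 0.0186), Rhox6 by −2.62 ± 0.34 (adjusted p = 0.0166) and Khdc3 by −2.10 ± 0.30 (adjusted p = 0.0245). Stra8, a retinoic acid-induced gene of meiotic entry, was lower by −1.81 ± 0.14 (adjusted p = 0.00361) and Rbm44 by −1.80 ± 0.16 (adjusted p = 0.00556). Higher in TiPSC were the imprinted gene Mest (1.30 ± 0.15, adjusted p = 0.0108), Acp5 (1.34 ± 0.14, adjusted p = 0.00846), Hunk, a protein kinase gene (1.53 ± 0.15, adjusted p = 0.00771), and Herpud1 (1.499 ± 0.25, adjusted p = 0.0441; chromosome 8). Csrnp3 had the largest rise of a named gene past the threshold (1.67 ± 0.28, adjusted p = 0.0441), and Myl9 (1.215 ± 0.20, adjusted p = 0.0396), Mcf2l on chromosome 8 (1.198 ± 0.21, adjusted p = 0.0492), Rida (1.12 ± 0.18, adjusted p = 0.0396), Cthrc1 (1.05 ± 0.17, adjusted p = 0.0397) and Sgce (1.025 ± 0.18, adjusted p = 0.04995) were higher too. Apod was lower (−1.98 ± 0.21, adjusted p = 0.00771). The polycomb genes Bmi1 (−1.10 ± 0.19, adjusted p = 0.0461) and Jarid2 (−0.57 ± 0.09, adjusted p = 0.0346) were lower, the 2 of 34 in a list that did not pass (median 0.08, mean −0.07, adjusted p = 0.400).

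Between TiPSC and ESC 115 genes passed the threshold in the limma fit, 53 higher and 62 lower in TiPSC, and 34 differed at least 2-fold (11 higher, 23 lower). The count was 12 without TiPSC 1, 19 without TiPSC 2, 17 without ESC 2 and 57 without ESC 3, and 3038 without ESC 1. Of the 31 named genes past the threshold 7 to 31 still passed with 1 array left out. A fit of the 6 compared arrays alone left 1 of the 115 genes and 1 of the 31 named genes. With the mean of all probe sets of a gene it was 65, and without the genes of chromosomes 8, 11, X and Y it was 93.

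Against ESC, 11 lists were called in TiPSC, and none with an estimated correlation (lowest adjusted p = 0.479). Germline genes were lower (median −0.49, adjusted p = 4.41e-08), with Rhox9, Rhox6 and Taf7l (−1.75 ± 0.28) past the threshold of 25 and 11 adjusted over the list alone. For germline genes adjusted p = 0.479 with an estimated correlation, in a range of 2.93e-09 to 0.479 over the alternatives. The Dlk1-Dio3 list was lower (adjusted p = 1.08e-04), with 3 of 4 members past the threshold over all genes and over the list alone. For the Dlk1-Dio3 list adjusted p = 0.479 with an estimated correlation, in a range of 1.54e-05 to 0.479 over the alternatives. X-linked dosage genes were lower (median −0.35, adjusted p = 6.32e-10), with 0 of 18 past the threshold over all genes and 12 adjusted over the list alone, in a comparison where chromosome X was at 0.65 in ESC 2 and ESC 3 but at −0.15 in ESC 1. For X-linked dosage genes adjusted p = 0.479 with an estimated correlation, in a range of 3.46e-13 to 0.479 over the alternatives. Fibroblast and feeder markers were higher (median 0.45, adjusted p = 2.31e-06): of 38, the collagen gene Col5a2 (0.90 ± 0.16) and Ccn1 (0.61 ± 0.09) rose and Sparc (−0.78 ± 0.08) fell, and 15 rose and 1 fell adjusted over the list alone. For fibroblast and feeder markers adjusted p = 0.479 with an estimated correlation, in a range of 9.74e-09 to 0.479 over the alternatives. Stress and immediate early genes were higher (median 0.45, adjusted p = 0.000277), with 0 of 23 past the threshold over all genes and 8 adjusted over the list alone. For stress and immediate early genes adjusted p = 0.479 with an estimated correlation, in a range of 2.08e-05 to 0.479 over the alternatives.

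The remaining calls between TiPSC and ESC each depended on particular arrays. Endoderm genes were lower (median −0.32, adjusted p = 0.00393), with Amn, an endocytic receptor subunit gene (−1.25 ± 0.22), and Sparc past the threshold of 22 and 3 adjusted over the list alone. For endoderm genes adjusted p = 0.479 with an estimated correlation, in a range of 1.38e-05 to 0.857 over the alternatives. Without ESC 1, where the endoderm regulator Gata6 was at 7.01 against 4.09 in ESC 2 and 3.89 in ESC 3, the adjusted p was 0.857. The 2-cell-like genes were lower (median −0.92, adjusted p = 0.0113) with 0 of 6 past the threshold over all genes or over the list alone, and without ESC 2 the adjusted p was 0.162. For the 2-cell-like genes adjusted p = 0.479 with an estimated correlation, in a range of 0.000572 to 0.479 over the alternatives. Trophoblast genes were lower (median −0.12, adjusted p = 0.0202), with 0 of 14 past the threshold and 3 adjusted over the list alone, and the call ended without TiPSC 2 (adjusted p = 0.106) or ESC 1 (adjusted p = 0.286). For trophoblast genes adjusted p = 0.479 with an estimated correlation, in a range of 0.00165 to 0.479 over the alternatives. Cholesterol genes were higher (median 0.17, adjusted p = 0.0175), with 0 of 19 past the threshold and 6 adjusted over the list alone, and ended without TiPSC 3 (adjusted p = 0.241) or ESC 1 (adjusted p = 0.286). For cholesterol genes adjusted p = 0.479 with an estimated correlation, in a range of 0.000672 to 0.479 over the alternatives. Smooth muscle genes were higher (median 0.16, adjusted p = 0.0476), with 0 of 10 past the threshold and 1 adjusted over the list alone, and ended without TiPSC 3 (adjusted p = 0.241), ESC 2 (adjusted p = 0.162) or ESC 3 (adjusted p = 0.0720). For smooth muscle genes adjusted p = 0.479 with an estimated correlation, in a range of 0.00918 to 0.479 over the alternatives. Glycolysis genes were higher (median 0.13, adjusted p = 0.0482), with 0 of 23 past the threshold over all genes or over the list alone, and ended without TiPSC 1 (adjusted p = 0.0889), TiPSC 2 (adjusted p = 0.109), ESC 2 (adjusted p = 0.340), ESC 3 (adjusted p = 0.0720) or the genes of chromosomes 8, 11, X and Y (adjusted p = 0.0811). For glycolysis genes adjusted p = 0.586 with an estimated correlation, in a range of 0.00507 to 0.586 over the alternatives. Leaving out the genes below the median mean level ended the calls of smooth muscle (adjusted p = 0.144), trophoblast (adjusted p = 0.115), glycolysis (adjusted p = 0.161) and cholesterol genes (adjusted p = 0.108), and the mean of all probe sets that of smooth muscle genes (adjusted p = 0.112). Of the 11 calls fry kept that of the Dlk1-Dio3 list.

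Genes past the threshold in both comparisons against ESC numbered 30, with 8 higher in both induced lines, 15 lower in both and 7 opposite. Acp5 was higher in both, and Rian, Meg3, Mirg, Ipp, Cdkn2a and Amn were lower in both. Of these, Rian, Meg3, Mirg and Amn lie on chromosome 12, and Ipp and Cdkn2a on chromosome 4. Agtrap and Efcab7, lower in both, and Crocc and Iqcc, higher in both, lie on chromosome 4 too. They are outside the naming rule and given for their position. Most other shared genes lie on other chromosomes. Whether a difference between the lines used gave this grouping was not tested. Between ViPSC and TiPSC themselves Rian differed by 0.02 (adjusted p = 0.991) and Ipp by 0.13 (adjusted p = 0.751). Independent lists of these sizes would share 0.769 higher and 0.429 lower genes. Simulated data without effects shared 0, but without effects hardly any gene can pass in either comparison. That count therefore cannot show how many shared genes the common ESC arrays give. Both comparisons use the same 3 ESC arrays, which are too few to split, so part of the excess can come from the shared controls. The covariance of the log2 differences across genes was 0.0383 against 0.0116 in the simulations, while their correlation of 0.439 was below the simulated mean of 0.498.

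The other 16 lists passed camera in none of the 3 comparisons. Of 38 core and naive pluripotency genes 0 passed between ViPSC and TiPSC over all genes or over the list alone (list median 0.02, adjusted p = 0.629), 1 passed between ViPSC and ESC, Alpl, alkaline phosphatase (0.43 ± 0.09, adjusted p = 0.0407), and 0 between TiPSC and ESC. Between ViPSC and TiPSC the adjusted p was 0.819 for cardiac transcription factors (median −0.04 with an upward test direction, 0 of 22 past the threshold), 0.873 for sarcomere genes (median −0.09, mean 0.05, upward) and 0.851 for calcium, channel and hormone genes (median −0.05, mean 0.01, downward). In the same comparison it was 0.365 for primed epiblast genes (median −0.21), 0.99996 for primitive streak and mesoderm genes (median −0.09), 0.819 for neural genes (median −0.14) and 0.195 for Hox genes (median −0.11). Of 17 primed epiblast genes 2 were higher in ViPSC, Dnmt3a and Foxd3 (0.59 ± 0.14, adjusted p = 0.0486), and 2 were lower, Fgf15 (−1.10 ± 0.19, adjusted p = 0.0152) and Tead2 (−0.705 ± 0.16, adjusted p = 0.0346). The adjusted p was 0.609 for blood and macrophage genes (median −0.04, mean 0.14), where Csf1r (1.54 ± 0.29, adjusted p = 0.0196) and Cd68 (1.37 ± 0.27, adjusted p = 0.0235; chromosome 11) rose, 0.819 for keratinocyte genes (median −0.01, mean 0.03) and 0.819 for skeletal muscle genes (median −0.02, mean 0.05). It was 0.937 for the other imprinted genes (median −0.14, mean 0.02; 3 of 37 higher and 3 lower), 0.819 for X inactivation genes (median 0.03, mean −9.69e-04), 0.828 for cell cycle genes (median −0.04) and 0.819 for the Wnt, LIF and TGF-beta targets (median −0.07).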

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

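The tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the arrays and the test for feeder cells in TiPSC, which was written when the median of the TTF-high genes was known but its own value was not. The gene and list tests between ViPSC and TiPSC were planned, and the test of probe sets without a single gene symbol was not.

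Genes that moved in opposite directions against ESC in the 2 kinds of induced cells are given with their difference, ViPSC minus TiPSC. These genes and the trophoblast list were chosen for opposite calls against the same ESC arrays, which makes a large difference and a small p follow, so the p values are no separate evidence. The difference was 2.20 for Fam167a (adjusted p = 0.000537), 1.67 for Gjb5 (adjusted p = 0.000379), 1.34 for Ms4a10 (adjusted p = 0.000879), 1.245 for Nsrp1 on chromosome 11 (adjusted p = 0.000537), 2.87 for Rbm44 (adjusted p = 0.000263), 1.45 for Slc25a20 (adjusted p = 0.000879) and 1.14 for Tmem37 (adjusted p = 0.000537). All 7 are the opposite calls among the 30 shared ones, and those other than Rbm44 lie outside the rule for named genes and are given because of their values. The trophoblast list, up against ESC in ViPSC and down in TiPSC, differed by a median of 0.466 (adjusted p = 6.24e-07, with adjusted p = 0.278 with an estimated correlation and a range over the alternatives of 2.20e-08 to 0.278).

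Probe sets without a single gene symbol took no part in the gene comparisons and also held differences. Of 10092 such probe sets, 142 passed between ViPSC and TiPSC (101 higher), 46 between ViPSC and ESC (37 higher) and 5 between TiPSC and ESC (1 higher).

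Expression of whole chromosomes stood apart in some arrays. For chromosome 11 in ViPSC against TiPSC, a few co-regulated clusters are argued against by 10 of 10 position bins with a median above 0.2, scaling between arrays by medians on chromosomes other than 8, 11, X and Y of −0.09 to −0.0089 without centring (largest size 0.0881, against 0.44 on chromosome 11), and transcripts kept from myocytes by a median of 0.429 over 343 expressed chromosome 11 genes that were not higher in VM than in TTF. The bin medians ran from 0.39 to 0.505, under the 0.585 of a full 3-to-2 ratio, so an extra copy of chromosome 11 in the ViPSC arrays is a candidate explanation, which DNA would have to show. A raised chromosome 11 was not particular to ViPSC. ESC 3 had a median of 0.19, with bins of 0.079 to 0.284, against −0.17 in ESC 1 and −0.20 in ESC 2. An extra copy of chromosome 8 in TiPSC 3 may explain its bins at 0.424 to 0.502, and 2 active X chromosomes in ESC 2 and ESC 3 may explain lowest bins of 0.503 there, where the highest bin of the other arrays was −0.0722. Whether such changes arose in culture, came with the cell of origin or differed between clones stays open, as each group may hold 1 line.

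Meg3, Rian and Mirg were lower in both kinds of induced cells than in ESC. Feeder cells left in the ESC arrays would raise fibroblast genes there, but the fibroblast and feeder list had medians of 0.107 and 0.455 in the induced minus ESC comparisons. A sequence variant under single probe sets would lower few of them, but 11 of the 17 probe sets of these genes were lower by at least 1 log2 unit in both comparisons, and 17 were lower in both. This test, written with the probe set values in view, took the place of an earlier test of X chromosome dosage, which had argued against dosage but rested on 1 ESC array and was dropped for that reason, so dosage stays open. A difference between induced and embryonic stem cells may account for the pattern, and a difference between the lines used stays open too, since neither was tested and the same 3 ESC arrays serve both comparisons.

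TTF-high genes were lower in ViPSC than in TiPSC, by a median of −0.107 against −0.035 over all genes. Feeder cells left in TiPSC could give this, since feeders are fibroblasts, although differential plating was meant to remove them. Of 45 TTF-high genes abundant in TTF and outside chromosomes 8, 11, X and Y, 75.6% were lower in ViPSC, between the bounds set beforehand. Their median excess in TiPSC over ViPSC was 0.373% of the TTF level on the linear scale, unlike the residuals above, which are on log2. Transcripts kept from tail tip fibroblasts would lower the genes outside the cell type lists, whose median was −0.0968 over 435 genes, but feeders would do the same. These explanations cannot be told apart here.

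The 6 arrays of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. As many genes as in the real split were found in 1 of 10 splits, the real one itself, in each comparison. In limma the real split gave 1024, 390 and 115 genes and the highest of the others 0, 0 and 0, with up to 499, 1818 and 2754 genes at an unadjusted p under 0.05 in the others. Each of the other splits mixes arrays of both groups, so a real group difference widens its spread. Their counts of 0 are therefore no measure of what chance would give. No other tool was run on the splits.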

How the results depend on the processing

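The alternative without the genes of chromosomes 8, 11, X and Y was chosen after the data were seen, and the other alternatives before. Of 1894 values of the 131 named genes past the threshold, 1375 kept their side of it, 519 lost it in the same direction and 0 reversed. Most of these values could not reverse. All genes past the threshold had arrays without overlap, so leaving out an array keeps the direction. Several other fits change the spread or the genes tested but not the difference. Of the values of called lists 213 kept the call and 94 lost it. Where no reason is given, the cause was not tested. For genes between ViPSC and TiPSC, ViPSC and ESC, and TiPSC and ESC, a difference of at least 1 log2 unit as well left 173, 78 and 34, as a stricter condition. The fit of the 6 compared arrays gave 2621, 73 and 1, and leaving out 1 array 207 to 874, 22 to 2519 and 12 to 3038. Without the genes of chromosomes 8, 11, X and Y there were 607 and 184 for the first comparisons (fewer genes). Every probe set gave 1635 between ViPSC and TiPSC, and the mean of all probe sets 65 between TiPSC and ESC. Replicate numbers in the labels showed no pairing (same-number correlations across genes −0.19 to 0.0996). A replicate block gave 623, 103 and 9 genes, of which 593, 98 and 8 were shared with the fit without it, and kept 52 of 65, 15 of 35 and 6 of 31 named genes. Called lists numbered 0, 0 and 0 with an estimated correlation (2, 3 and 2 at an unadjusted p under 0.05), 4, 1 and 1 by fry, 4, 2 and 6 without the genes below the median mean level (fewer genes), 4 and 4 for the first comparisons without the genes of the 4 chromosomes, and 5 to 9, 5 to 9 and 8 to 12 without 1 array. VM-high genes passed with VM against TTF alone (−0.0083, adjusted p = 0.0478) and without the genes of low mean (0.0030, adjusted p = 0.0435), and had medians of −0.0257 to 0.00069 without 1 array. TTF-high genes no longer passed with an estimated correlation (−0.107, adjusted p = 0.203), with a size of 1 log2 unit (−0.0755, adjusted p = 0.141) and without TiPSC 1 (−0.0997, adjusted p = 0.119), in a range of medians of −0.125 to −0.0925 without 1 array. Counting 1 or 3 log2 units gave 4413 or 852 genes for VM against TTF (918 without the genes of low mean), 5555 or 1099 for ViPSC against VM and 4807 or 893 for TiPSC against TTF, as a looser or stricter condition. The residual of VM-high genes, 0.0313% in ViPSC and 0.298% in TiPSC as reported, was 0.729% in ViPSC and 1.19% in TiPSC with a size of 1 log2 unit. Without the genes of low mean it was 2.84% and 1.35%, and that of TTF-high genes 0.863% and 4.40% in ViPSC and TiPSC. Without 1 array the VM-high residual in ViPSC was 0.208% to 0.352%. Reversed values were all of genes not past the threshold. Meg3 between ViPSC and TiPSC was −0.0672 with the mean of all probe sets and −0.234 to 0.351 without 1 array, Ftx between ViPSC and TiPSC −0.398 to 0.126 without 1 array, and Jpx −0.0059 and Kdm5c 0.0984 with the mean of all probe sets. Without 1 array Gata6 ranged from −1.19 to 0.368 between ViPSC and ESC and from −1.26 to 0.303 between TiPSC and ESC (both highest without ESC 1), and Myh3 from −0.93 to 0.0527 between TiPSC and ESC (highest without ESC 3). The number of arrays and values near background limit what can be detected.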

Other observations

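The values in this part were chosen after the data were seen, and none was tested.

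The ESC arrays differed from each other in genes of other states. In ESC 2 the 2-cell-like list had a median of 2.27 against the mean of the 9 pluripotent arrays, while the other arrays lay between −0.440 and −0.027. Tcstv1, a gene of that state, was at 7.22 in ESC 2. In ESC 1 the endoderm regulator Gata6 was at 7.01, against 4.09 in ESC 2 and 3.89 in ESC 3.

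Genes of the sex chromosomes differed between arrays of the same group. The Y-linked gene Eif2s3y was at 3.73, 3.89 and 4.22 in ESC, at 5.11 in TiPSC 1 and at 8.64 and 8.80 in TiPSC 2 and TiPSC 3. In the source cells, VM had Eif2s3y at 8.28 with Xist at 11.50, and TTF had 8.39 with 11.06. Ipp stood at 9.95, 10.63 and 10.64 in ESC and at 5.38 in TTF and 4.89 in VM.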
